A study of Mus musculus with 8 samples.

How the data were processed

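RNA from primary cultures of mouse kidney proximal tubule cells was measured on 8 one-colour Agilent gene expression arrays, 4 from cells given the vehicle DMSO and 4 from cells given 1 uM GW4064 for 24 h. The spot brightness was deposited as intensity, background-subtracted by the scanner software Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.7 and limma. A table of log2 values for the whole series was also deposited by the authors, with its scale and centring unstated. Its sorted columns differed from one another by at most 0.01, every column had a median of 6.598, and each column correlated at 0.9996 or more with the log2 signal of its own array and at 0.9934 or less with any other array. It therefore held log2 signals brought to 1 common distribution, as quantile normalization gives, with no centring of genes, and it was used only as an alternative.

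Each array held 44397 spots, of which 1377 were controls and were left out, as were spots marked as outliers by the scanner software (98 to 174 per array). Spots of 1 probe were averaged on the log2 scale, which gave 39429 probes. Values were log2 of the processed signal minus the array's 75th percentile. A probe was kept if its signal was well above background on at least 4 of the 8 arrays and if no array had all its spots of that probe marked (85 probes had), which left 24756 probes. Accessions in the files were matched, without versions, to the gene table of mouse assembly GRCm38.p6, used for names only; 27234 of the probes (69.1%) received a symbol and 12195 did not. The file headers name build mm9, so no coordinates are given. For each gene the brightest kept probe was used, which left 14476 genes. Of the 3006 called genes, 751 had several kept probes, and in 681 of these all probes went the same way.

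Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate. Errors of log2 fold changes are standard errors from this fit, with n = 4 arrays per group. Where no array of a group had a probe well above background, the fold is a bound ("at least"): the bright group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. The 30 gene lists, written from general knowledge before the data were examined, were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The number of arrays limits the precision. On data simulated for the GW4064 against DMSO comparison over 14476 genes, the fit recovered 82 of 100 genes changed by 0.5 on the log2 scale. It recovered 95 of 100 changed by 1, and called 10 unchanged genes. No other genes were changed, far fewer than the 3006 called in the data, and genes were drawn independently. These rates need not hold in the real data. In a simulation of 30 random lists, with every gene drawn independently, camera recovered the 1 raised list and called 0 of the others. Because it held no correlation between genes, it cannot show how often camera calls unchanged lists in the real data.

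The rule for the genes named was fixed before the data were examined. It took the FXR gene Nr1h4 and 6 known targets, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and the most abundant member of cell marker lists, taken as the one with the brightest probe over all arrays, although brightness of different probes does not rank transcripts by abundance. Genes outside the rule are said to be chosen after their values were seen. The values of 2 genes that the rule takes are not reported here.

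Alternatives covered background correction with normexp (offset 50), quantile normalization, median centring, no filter and a filter on all 8 arrays, the mean of a gene's probes, probes in place of genes, blocks for replicate number, slide and scan date, array weights, a trended robust fit, the deposited log2 table and leaving out each array. Slide and scan date split the arrays in the same way, so their blocks are the same check, though counted as separate settings. Normexp was planned on mean spot signals and was run on median spot signals, which the files hold. The labels do not say whether the 4 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.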

Results

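Gene expression was measured in primary cultures of proximal tubule cells, the reabsorbing epithelium of the nephron, grown to confluence from kidney cortex of male 6-week-old mice. In serum-free medium, 4 samples received DMSO and 4 received 1 uM GW4064 for 24 h. GW4064 is a synthetic agonist of FXR, the nuclear receptor for bile acids. Between 61.4% and 65.7% of probes per array were well above background. The 75th percentile of the processed signal was 1626 ± 187 (SD, n = 4) with DMSO and 1412 ± 207 (SD, n = 4) with GW4064. The arrays lay on 2 slides of 4, each with 2 DMSO and 2 GW4064 samples. DMSO samples always took the first 2 places on a slide, so place and treatment were confounded.

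The comparison asked which transcripts the FXR agonist changed. The organic solute transporter subunits Slc51a and Slc51b, which carry bile acids across the basolateral membrane, rose 120.6-fold (log2 fold change 6.91 ± 0.16 SE, n = 4 per group) and 10.6-fold (3.40 ± 0.07). Fabp6, the ileal bile acid binding protein, was not well above background on any of the 4 DMSO arrays and was at least 61.4-fold higher with GW4064. Nr1h4, which encodes FXR, fell by 0.45 ± 0.05 on the log2 scale. Nr0b2 was well above background on 1 of 8 arrays, and Abcb11 and Fgf15 on 0 of 8, so these 3 targets were not tested.

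Across 14476 genes, 3006 passed an adjusted p of 0.05 in limma, 1711 higher and 1295 lower with GW4064. The groups did not overlap for 2846 of the called genes. Of all tested genes, 26.2% had no overlap, against 2.86% by chance. Most changes were small, with a median size of 0.30 on the log2 scale. At least 2-fold changes numbered 188 (143 higher, 45 lower), and at least 4-fold changes 35 (32 higher, 3 lower). With slide as a block 2856 genes passed, of which 2718 were among the 3006. Slide 1 alone called 966 genes and slide 2 alone 220.

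**Figure D1:**
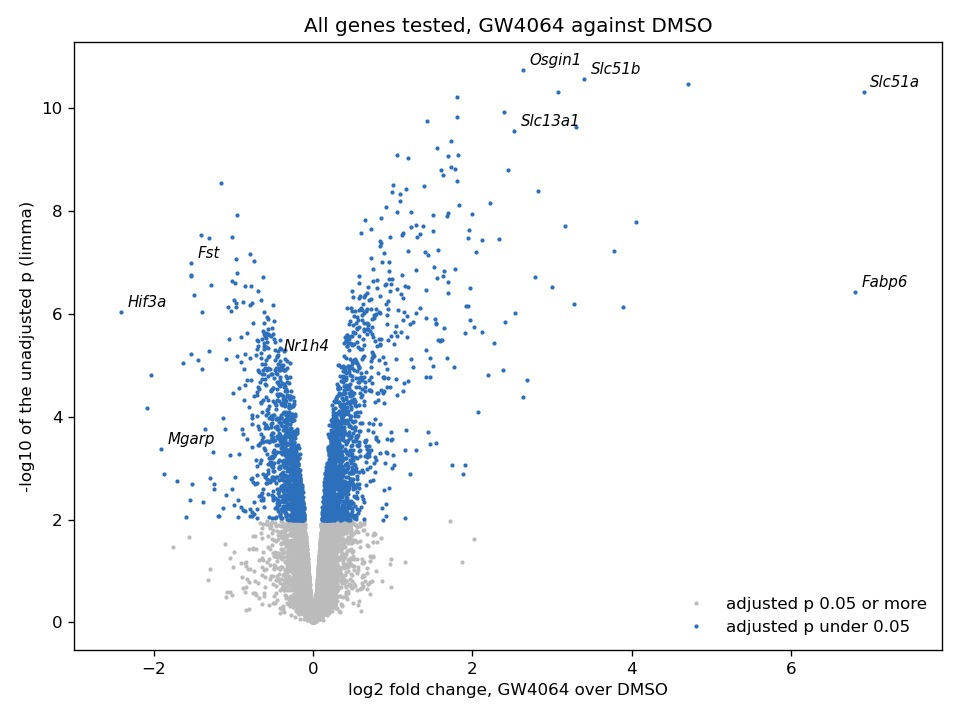
Each point is 1 of 14476 genes, with the log2 fold change of GW4064 over DMSO on the x axis and the negative log10 of the unadjusted limma p on the y axis; blue points passed an adjusted p of 0.05. Slc51a (6.91) and Fabp6 (fitted value, not well above background on any DMSO array) lie farthest to the right, and Hif3a (-2.42) farthest to the left.

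Other large rises included the retinoid carriers Rbp4 (13.7-fold, 3.78 ± 0.21 log2) and Crabp1 (9.71-fold, 3.28 ± 0.24). Rbp4 was well above background on 1 of 4 DMSO arrays. Rarres2, the chemerin precursor, rose 8.94-fold, Alpl, tissue-nonspecific alkaline phosphatase, 8.43-fold, and Synm, an intermediate filament protein, 9.83-fold. Hnf4aos, antisense to the epithelial transcription factor gene Hnf4a, rose 14.8-fold and was well above background on 2 of 4 DMSO arrays. Crygs, Zdhhc19 and Sectm1b were not well above background on any DMSO array and were at least 12.4-fold, 6.22-fold and 4.13-fold higher. Among falls, Hif3a, a hypoxia-inducible factor subunit, was 5.34-fold lower (-2.42 ± 0.19 log2). The glycogen-targeting phosphatase subunits Ppp1r3c and Ppp1r3g were lower, Ppp1r3c by at least 2.47-fold and Ppp1r3g 2.94-fold (-1.55 ± 0.40 log2). Abi3bp and Ldc1 were at least 2.24-fold and 2.63-fold lower. Mgarp, a mitochondrial protein, was 3.75-fold lower, Fst, the activin antagonist follistatin, 2.90-fold, Ube2ql1 2.91-fold, Icos 2.91-fold and Ankrd34b 3.12-fold. Ip6k3 was 3.27-fold lower (-1.71 ± 0.38 log2) and Hrg 3.02-fold (-1.60 ± 0.47), the latter near the threshold (adjusted p = 0.0458 in limma). With GW4064, Ip6k3 was well above background on 1 of 4 arrays and Hrg, Icos and Ppp1r3g on 3 of 4.

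**Figure D2:**
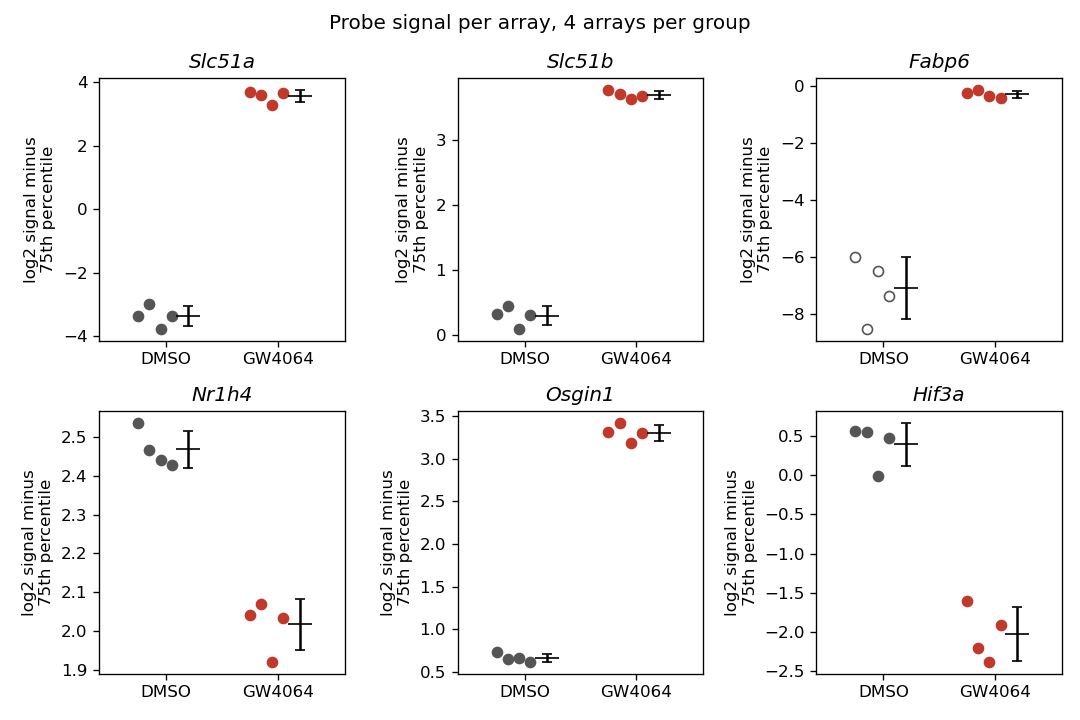
The y axes give log2 signal minus the array's 75th percentile, on a scale of its own for each gene; points are the 4 arrays per group, open where the probe was not well above background on any array of the group, and bars show mean and SD. The groups do not overlap for any of the 6 genes.

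For gene lists fixed in advance, 14 of 30 passed camera at an adjusted p of 0.05 with a preset correlation, 10 higher and 4 lower. Some lists share genes, such as Slc51a, Slc51b and Fabp6 in the FXR target and bile acid lists, so the calls are not independent. With an estimated correlation 0 passed (lowest adjusted p = 0.0938, 3 lists under an unadjusted p of 0.05), and fry called 16, 15 higher and 1 lower, the hypoxia list. The lists of interferon, of cell cycle, and of gluconeogenesis and glycolysis, lower by camera, did not pass fry (adjusted p = 0.131, 0.131 and 0.337). Nor did the ribosomal protein list, higher by camera (0.0695). Passing fry upward but not camera were fatty acid oxidation (adjusted p = 0.0142), fatty acid and triglyceride synthesis (0.0203), inflammation (0.0113), unfolded protein response (0.0232), xenobiotic metabolism (0.0125) and autophagy (0.0060). With slide as a block 14 passed.

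Of 32 measured targets known to be induced by FXR, 17 rose, 2 fell and 13 did not pass (19 and 4 adjusted over the list alone). Besides Slc51a, Slc51b and Fabp6, complement C3 rose 7.09-fold. The list passed camera (adjusted p = 2.66e-05; adjusted p = 0.0938 with an estimated correlation). In the bile acid synthesis and transport list 7 of 19 genes rose and 2 fell (9 and 3 adjusted over the list alone), with camera's adjusted p = 0.0276 and an adjusted p = 0.314 with an estimated correlation. Its call was lost on slide 1 alone (adjusted p = 0.0583), without a filter on dim probes (adjusted p = 0.0551) and with the filter on all 8 arrays (adjusted p = 0.116).

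Proximal tubule markers rose as a list. Of 34, 20 rose, 4 fell and 10 did not pass (25 and 4 adjusted over the list alone). The sulfate transporter Slc13a1 rose 5.74-fold (2.52 ± 0.07 log2), the creatine synthesis enzyme Gatm 3.87-fold, the urea cycle enzyme Ass1 2.17-fold and the transcription factor Hnf4a 1.80-fold. Pdzk1, whose probe was the brightest of the list over all 8 arrays, had a log2 fold change of 0.23 ± 0.08 and did not pass. The 4 that fell, named after their values were seen, were Kap (-0.68 ± 0.11), Acsm2 (-0.65 ± 0.16), Pax8 (-0.29 ± 0.05) and Mme (-0.27 ± 0.06). Camera's adjusted p was 1.63e-08, with an adjusted p = 0.630 with an estimated correlation. The mean log2 fold change was 0.58 on slide 1 and 0.71 on slide 2.

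Markers of other cells moved with the treatment too. Of 17 leukocyte and macrophage markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera's adjusted p = 0.00273, adjusted p = 0.498 with an estimated correlation). They included the macrophage receptor Csf1r (1.68-fold), Cd74 (1.43-fold), Coro1a (1.27-fold) and C1qb (1.21-fold). Ptprc, named after its values were seen, was the only marker of the list below 0 (1.87-fold lower, -0.90 ± 0.54 log2) and did not pass. Itgam, also named afterwards, had a log2 fold change of 0.03 ± 0.11 and did not pass. Of 11 endothelial markers 4 rose and 0 fell (5 and 1 adjusted over the list alone), Esam by 1.99-fold and Plvap by 1.29-fold; Egfl7, the marker with the brightest probe, had a log2 fold change of 0.09 ± 0.07 and did not pass. The list's adjusted p in camera was 0.0181, with an adjusted p = 0.497 with an estimated correlation. The endothelial call was lost on slide 2 alone (adjusted p = 0.0741). Fibroblast and pericyte markers (4 higher, 1 lower of 14) and markers of other nephron segments and podocytes (1 higher, 3 lower of 19) did not pass. Among the former Fbln2 was 1.58-fold lower and Tagln, a smooth muscle marker, rose 1.44-fold. Among the latter the magnesium channel Trpm6 rose 1.40-fold and Umod, a thick ascending limb marker, was 1.63-fold lower.

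Genes of the NRF2 antioxidant response rose, 18 of 36 with 0 lower (19 and 2 adjusted over the list alone). The oxidative stress growth inhibitor Osgin1 rose 6.21-fold (2.64 ± 0.05 log2), the glutathione transferases Gsta4 and Gsta2 3.05-fold and 2.62-fold, and glutathione reductase Gsr 1.57-fold. Camera's adjusted p was 2.75e-08 (adjusted p = 0.0938 with an estimated correlation). Among 4 aryl hydrocarbon receptor targets, Nqo1, which also counts in the NRF2 list, rose 1.85-fold and Cyp1b1 rose 1.33-fold. Aldh3a1 (0.35 ± 0.15 log2) and Tiparp (-0.01 ± 0.06) did not pass. The aryl hydrocarbon receptor list gave 2 and 0 adjusted over the list alone, camera's adjusted p = 0.0369 and an adjusted p = 0.376 with an estimated correlation.

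Hypoxia response genes were lower as a list, with 11 of 22 down and 1 up (15 and 1 adjusted over the list alone). The glucose transporter Slc2a1 was 1.43-fold lower, the glycolytic regulator Pfkfb3 1.49-fold lower and the mitophagy receptor Bnip3l 1.26-fold lower, whereas Pfkfb4 rose 1.29-fold. Camera's adjusted p was 5.59e-06, with an adjusted p = 0.630 with an estimated correlation. Of 31 interferon response genes 8 fell and 0 rose (13 and 0 adjusted over the list alone). Oas2, an antiviral oligoadenylate synthetase, was 2.38-fold lower, Oasl1 1.65-fold, Herc6 1.27-fold and Irf9, a subunit of the interferon-activated transcription complex, 1.27-fold. Camera's adjusted p was 9.41e-05, with an adjusted p = 0.630 with an estimated correlation. DMSO replicate 3 had an interferon list mean of -0.29, against 0.31 to 0.40 on the other DMSO arrays and -0.31 to -0.11 with GW4064. The interferon difference was -0.56 on slide 1 and -0.26 on slide 2, which held that sample, and the hypoxia difference -0.49 and -0.27.

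**Figure D3:**
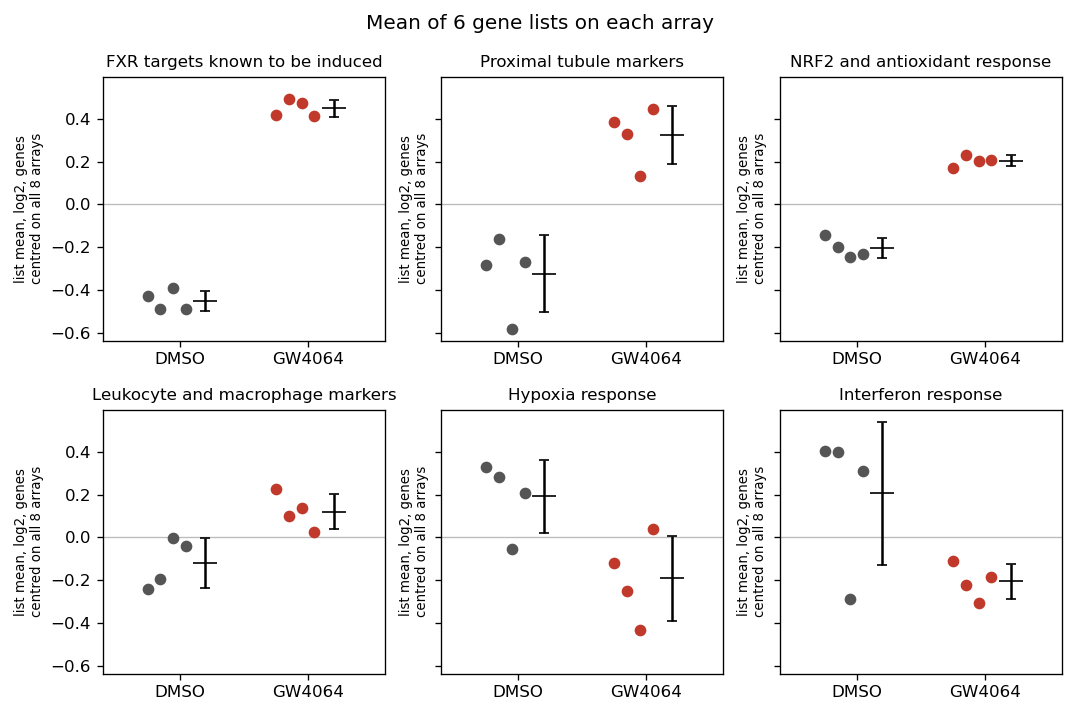
The y axes give the mean of a list's genes on each array, in log2 units after centring each gene on all 8 arrays; points are the 4 arrays per group and bars show mean and SD. FXR target, proximal tubule, NRF2 and leukocyte list means separate the groups, while 1 DMSO array lies among the GW4064 arrays for interferon genes (-0.29).

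In metabolism, 6 of 25 cholesterol synthesis and uptake genes rose and 0 fell (6 and 0 adjusted over the list alone; camera's adjusted p = 0.0216, adjusted p = 0.497 with an estimated correlation). Acat2, which starts sterol synthesis from acetyl-CoA, rose 2.27-fold, and the mevalonate pathway genes Mvd and Mvk 1.45-fold and 1.28-fold. Of 21 gluconeogenesis and glycolysis genes 7 fell and 2 rose (8 and 3 adjusted over the list alone). The gluconeogenic genes Pcx, pyruvate carboxylase, and G6pc, glucose-6-phosphatase, rose 2.39-fold and 2.72-fold. Besides Pfkfb3 and Slc2a1, the genes that fell were Pfkp, Pgam1, Hk1, Pgk1 and Pkm, named after their values were seen. The list joins 2 opposed pathways, so its lower call does not mean that gluconeogenesis fell. Camera's adjusted p was 0.0497, with an adjusted p = 0.643 with an estimated correlation, and 0.0568 with slide as a block. The list's mean log2 fold change was only -0.02 (median -0.14), with -0.12 on slide 1 and 0.08 on slide 2, where the list did not pass (adjusted p = 0.472). Vnn1 (2.53-fold), Fgf21 (2.76-fold), the triglyceride enzyme Dgat2 (1.65-fold) and Pnpla3 (at least 1.91-fold) rose in lists that did not pass camera. Pnpla3 was not well above background on any DMSO array, and its bound equals its fitted fold. The lists were fatty acid oxidation and PPAR-alpha targets (9 higher, 2 lower of 29) and fatty acid and triglyceride synthesis (7 higher, 3 lower of 21). For the former camera's adjusted p was 0.298, and 0.0156 without a filter on dim probes.

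In the TGF-beta and extracellular matrix list 10 of 30 genes rose and 3 fell (11 and 3 adjusted over the list alone). Tgfbi rose 1.71-fold, Ccn1 1.29-fold and Col4a1, a basement membrane collagen, 1.27-fold, and Cdh2, N-cadherin, was 1.27-fold lower. Camera's adjusted p was 0.0309, with an adjusted p = 0.630 with an estimated correlation, and 0.0557 on slide 1 alone. Of 36 cell cycle genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), Rrm2 by 1.19-fold, Ccnb2 by 1.19-fold and Cdk1 by 1.23-fold; camera's adjusted p was 0.00622, with an adjusted p = 0.630 with an estimated correlation, and 0.136 on slide 2 alone. Of 36 cytosolic ribosomal proteins 2 rose (0 adjusted over the list alone; camera's adjusted p = 0.00273, adjusted p = 0.630 with an estimated correlation). They were Rps4x (1.11-fold) and Rpl13a (1.13-fold, with 1 of 3 probes in that direction), and the list did not pass after quantile normalization (adjusted p = 0.280).

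The remaining lists did not pass camera. Inflammation and NF-kB targets had 11 higher and 5 lower of 29, with Ccl7, a monocyte chemokine, up 3.08-fold and the growth factor Csf2 at least 1.80-fold higher. Nuclear receptors and cofactors had 6 higher and 7 lower of 32, with the xenobiotic receptor Nr1i2 up 2.89-fold. Xenobiotic metabolism had 4 higher and 3 lower of 19, with the sulfotransferase Sult1a1 up 3.50-fold; its median was -0.00099 and its mean 0.18. Osmotic response had 2 higher and 1 lower of 11, with the water channel Aqp1 up 1.95-fold; its median was -0.09, its mean 0.0069 and camera's direction down. Tubular injury and dedifferentiation had 5 each way of 23, with Sox9 up 1.60-fold and Cd24a 1.40-fold lower. Unfolded protein and integrated stress response had 9 higher and 5 lower of 37, p53 response and apoptosis 5 and 2 of 30 with Bcl2 up 1.60-fold, autophagy and lysosome 3 and 3 of 28 with Neu1 up 1.56-fold. Growth factor and immediate early response had 4 and 4 of 26, with Hbegf up 1.53-fold, heat shock proteins 2 and 1 of 16, and targets known to be repressed by FXR 1 and 0 of 7. In the mitochondrial respiratory chain list 0 rose and 1 of 34 fell, Cycs (1.13-fold lower; camera's adjusted p = 0.0549).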

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

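The tests of the dimmer GW4064 arrays and of equal folds of proximal tubule markers, and the reading used for the leukocyte test, were chosen only after the results were seen; the other tests were set out before theirs.

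Of the 274 groups of 4 arrays examined (list means, named genes and array measures), 20 (7.30%) had 1 array apart from the other 3, where chance gives about 5%. DMSO replicate 3 was that array in 8 of them. It was low for the interferon list mean (-0.29), Hif3a (-0.0082), Slc2a1 (3.05), Herc6 (-2.92), Slc5a3 (-1.10) and Dusp6 (3.27), and high for Fgf21 (-4.31) and Tagln (5.11). GW4064 replicate 3 stood apart for Crabp1 (-2.23), Fgf21 (-3.02), Ass1 (4.85), Tagln (5.64) and Nr1i2 (-1.14). The others were the ribosomal protein list mean in GW4064 replicate 1 (0.0099), Zdhhc19 in DMSO replicate 1 (-8.08), Acat2 in DMSO replicate 4 (-0.57), Eng (-2.92) and Gsta4 (1.82) in GW4064 replicate 4, and Cdk1 (-0.58) and Sult1a1 (-2.89) in DMSO replicate 2. Gene values are log2 signals minus the array's 75th percentile. A probe without a symbol, for transcript ENSMUST00000042042, rose 118.5-fold with GW4064; its accession did not match the gene table, so its gene is not named here.

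The first pattern is the count of 3006 genes. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many genes. The highest of the others gave 0 in limma (2033 at an unadjusted p under 0.05, against 4973). This argues against chance, but 1 of 35 is the smallest share that the test can give. Every other split mixed DMSO and GW4064 arrays, so any difference between the groups widened the spread within its sides and lowered its count. For lists 1 of 35 splits gave as many as the real 14, but another gave 12, so the number of lists past camera says much less than the number of genes. Place on the slide was confounded with treatment. The 7 spike-in RNAs well above background on all arrays differed between groups by a median of 0.025 after centring. The called genes, selected for their change, had a median of 0.30. The place difference within a treatment correlated with the treatment difference across genes at no more than 0.040. These values argue against place in hybridisation for bright probes and against a steady gradient. Dimmer spike-ins, left out of this test, differed by -0.12, -0.24 and 0.13 after centring. A step between places therefore stays open for dim probes. After quantile normalization 92.8% of called genes passed with the same sign, which argues against dimmer arrays; handling before labelling in the order of the places stays open.

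The second pattern is that the proximal tubule, leukocyte and endothelial marker lists were called higher by camera at the preset correlation, with 20 of 34, 5 of 17 and 4 of 11 members passing upward and 4, 0 and 0 downward; none of these calls held with an estimated correlation (adjusted p = 0.630, 0.498 and 0.497). A higher share of proximal tubule cells at the cost of other cells is argued against, but only as far as those calls go. Of the 4 other marker lists 2, leukocyte and endothelial, met the bound set beforehand. They had 16 of 17 and 10 of 11 members above 0 (exact two-sided sign test p = 0.000275 and 0.0117, which takes genes as independent). That test takes 0 as its reference, yet 93 olfactory receptor genes (Olfr) had a median of 0.08. Members slightly above 0 therefore need not show more of a cell type. Among the markers of these 2 lists with the brightest probes, Itgam (0.03), Kdr (0.16) and Egfl7 (0.09) did not pass, and Csf1r (0.75) did. More leukocytes could not be decided: the 5 brightest leukocyte markers had a median log2 fold change of 0.26 and 0 of 5 were at or below 0, yet only Csf1r passed. Read as 4 of 5 not rising, the bound set beforehand would exclude it; the reading by sign was chosen after the folds were seen, because a fold above 0 that misses the threshold does not show that a marker failed to rise. One common rise of all proximal tubule markers was not decided by the bound set beforehand. It asked for 3 of the 10 brightest at or below 0, and 2, Kap and Pax8, fell while 5 rose. In the test chosen afterwards, the 95% interval left out the list median of 0.60 for 26 of the 34 markers. Of these 13 lay below it and 13 above, a balance nearly fixed by taking the median from the same markers. An equal fold leaves out the median for about 5%. The 26 of 34 argue against an equal fold for all markers. That count does not show that no part of the rise came from a higher share of these cells.

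The third pattern is the lower interferon and hypoxia lists. The list means gave exact two-sided permutation p of 0.114 for interferon and 0.0571 for hypoxia, and both overlapped between groups, so culture-to-culture variation unrelated to treatment may account for either. For the other lists called lower the same test gave 0.0571 (cell cycle) and 0.857 (gluconeogenesis and glycolysis). Over all 30 lists the lowest adjusted p was 0.0612, from the smallest p that 70 arrangements can give, 0.0286. The interferon overlap came from DMSO replicate 3 alone. A response of these genes to GW4064 is the biological alternative, and it stays open.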

How the results depend on the processing

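The fits on slide 1 alone and slide 2 alone were chosen after seeing the data; the other alternatives were fixed before the data were examined. The 3006 genes became 2167 (no filter) to 3818 (probes in place of genes) under the planned settings with all arrays, and 2076 to 2827 with 1 array left out; quantile normalization gave 3008, of which 2789 were shared. Slide 1 alone gave 966 and slide 2 alone 220, with 4 arrays each. The 14 lists became 12 to 16 under the planned settings with all arrays, except 0 with camera's correlation estimated; the cause was not tested. With 1 array left out they were 11 to 15. Samples with the same replicate number had weakly correlated deviations (-0.13, -0.03, 0.19 and -0.02). The own number was the best match for 1 of them, replicate 3. With 4 samples per group this cannot show whether the samples were paired. With the replicate block 2322 genes and 13 lists passed, without the aryl hydrocarbon receptor list (adjusted p = 0.0559).

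Of 105 named genes, 96 were called, and 83 of these kept direction and call in every planned setting where they were tested. Of 14 called lists, 7 kept both in every planned camera setting with the preset correlation. The gluconeogenesis and glycolysis list was lost without DMSO replicate 1, 2 or 4 or GW4064 replicate 1, 2 or 3 (adjusted p 0.0509 to 0.178), and with the slide block, median centring (0.0600) and both other filters (0.0575 and 0.136). Cholesterol was lost without DMSO replicate 1 (adjusted p = 0.0510), cell cycle and aryl hydrocarbon receptor without DMSO replicate 2 (0.0505 each), TGF-beta without GW4064 replicate 3 (0.0806) or 4 (0.0603), and aryl hydrocarbon receptor without GW4064 replicate 4 (0.0678). The mitochondrial respiratory chain list passed downward in 10 planned settings, quantile normalization (0.0053) among them, and fatty acid oxidation upward without the filter (0.0156).

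By camera's direction no called result reversed. The mean of the gluconeogenesis and glycolysis list (-0.02) turned positive on slide 2 alone (0.080). It was also positive without DMSO replicate 1 (0.023) or 2 (0.012) or GW4064 replicate 3 (0.046). Uncalled results near 0 did reverse, given as mean log2 fold change. Tiparp gave 0.0034 with normexp, 0.0022 with the mean of probes, 0.011 with array weights and 0.046 on slide 1 alone, and with 1 array left out it ran from -0.044 to 0.034, above 0 without DMSO replicate 4 (0.020) or GW4064 replicate 3 (0.034). Heat shock proteins gave 0.00011 with normexp, 0.00092 with quantile normalization, 0.025 with array weights, 0.00063 with the deposited log2 values and 0.0039 on slide 1 alone, and with 1 array left out 0.025 to 0.041, with camera's direction turned without DMSO replicate 3 (0.029). On slide 1 alone p53 response gave 0.0048 and xenobiotic metabolism 0.14. Without the filter, targets repressed by FXR gave -0.12 and growth factor response 0.011. The causes were not tested. Low signal kept Nr0b2, Abcb11 and Fgf15 untested.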

Other observations

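Gene families defined by shared symbol stems were tested with camera, as a search fixed by no prior list. None of the 236 families of at least 8 members passed an adjusted p of 0.05 (26 had an unadjusted p under 0.05).

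Among kept probes without a symbol, 581 of 5699 passed the threshold, 270 higher and 311 lower. The correlation of log2 fold changes between slides was 0.76 across all genes, which are not independent replicates. In limma 0 genes had a change that differed between slides at an adjusted p of 0.05, with 542 at an unadjusted p under 0.05. With so few arrays of each group per slide the test has little power, so 0 does not show that the slides agree.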
